A study of Caenorhabditis elegans with 15 samples.

How the data were processed

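RNA was measured in whole C. elegans adults of 5 genotypes, with 3 libraries each: a wild type that carries an integrated reporter transgene, and cat-2(e1112), tbh-1(ok1196), tdc-1(n3419) and tph-1(mg280) mutants with the same transgene. Animals were grown at 20 °C with FUdR and collected 48 h after the L4 stage. The libraries were poly(A)-selected and read from 1 end. The submitters' processing notes state alignment with STAR 2.5.1a to the WS245 genome and an edgeR likelihood ratio test of each mutant against wild type. They also state that a batch effect led to the removal of 1 replicate of every genotype. The deposited table holds whole-gene read counts of the authors for 15 libraries. Neither the strand rule nor the rule for reads with several positions was given, so values of near-identical paralogs (msp, collagen and F-box genes) and of overlapping or antisense genes are uncertain. Whole-gene counts cannot check a partial lesion, which applies to tdc-1 and cat-2.

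The table listed 47096 genes, of which 46449 were matched to the Ensembl annotation of the same genome and 19788 had no read in any library. After the low-count filter of edgeR by group, 15863 genes were tested. Libraries held 29.8 to 38.8 M counted reads, with means of 32.9, 35.2, 32.4, 33.6 and 34.2 M in wild type, cat-2, tbh-1, tdc-1 and tph-1. At that depth 3 reads over a group equal 0.0281 to 0.0313 CPM (read counts scaled to the same library size), which was the floor for genes with no read in a group. Ribosomal RNA took 0.308 to 3.61% of reads. The biological coefficient of variation was 7.40%, with a median of 6.13 prior degrees of freedom, and replicates spread more than counting error (chi-square per degree of freedom 4.86 to 66.4).

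Counts were scaled with TMM and tested with the edgeR 4.0.16 quasi-likelihood test (robust, R 4.3.3) on all 15 libraries, with Benjamini-Hochberg adjustment within each of 6 comparisons and a threshold of 0.05. The comparisons were each mutant with wild type, tdc-1 with tbh-1 and cat-2 with tph-1. Values after CPM are SD over n = 3 libraries, and SE belongs to log2 changes. P-values measure spread among these samples, and intervals of read ratios cover counting error only. Populations of the same replicate number were grown at the same time, so whether the numbers pair the libraries was checked: residual correlation had a median of 0.0967 over 30 pairs with the same number and of -0.0781 over 60 other pairs. The ranges overlapped (-0.290 to 0.369 and -0.470 to 0.447), but the median was higher for the same number, so pairing stays possible. The fit without a replicate block had been chosen, and the fit with the block was an alternative. The main counts therefore make no allowance for pairing, and the block called more genes in every comparison.

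A set of 37 gene lists was fixed before the data were examined, as were the tests and the alternatives. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. Results are given for lists of amine synthesis, amine receptor, antimicrobial peptide, UDP-glucuronosyltransferase, cytochrome P450, muscle, collagen, sperm, oocyte and eggshell, vitellogenin, lectin, lysozyme, fatty acid enzyme, pathogen response, proteasome, ubiquitin and F-box genes. Genes were named by a fixed rule: the 4 mutated genes, the largest changes per comparison among genes with a mean of at least 1 CPM and group ranges that did not overlap, up to 4 members of each list described, and up to 10 genes changed in the most mutants. Pseudogenes were tested and not named.

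Alternatives were the likelihood ratio test, DESeq2 1.42.0, its size factors, TMM without the sperm, oocyte, vitellogenin and collagen lists, no filter, a mean of at least 5 CPM, the replicate block, only the 2 groups compared, and the omission of each library or replicate number. List counts without each library were added after the data were seen, as were a molting list of 25 genes and a test of the amine synthesis list without the 4 mutated genes. The test was checked on simulated data with 66 or 67 genes at each fold size: it recovered 62.7 to 80.6% of 1.5-fold, 83.6 to 98.5% of 2-fold and 97.0 to 100% of 4-fold changes, with 2 to 17 false calls. Sharing between mutants was compared with 20 simulated datasets in which only the controls were shared. GC content was not analysed here, since no genome sequence was at hand.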

Results

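Gene expression was measured by RNA sequencing in whole adult C. elegans that lack enzymes of biogenic amine synthesis. The 4 mutants were cat-2 (tyrosine hydroxylase, dopamine), tbh-1 (tyramine beta-hydroxylase, octopamine), tdc-1 (tyrosine decarboxylase, tyramine and octopamine) and tph-1 (tryptophan hydroxylase, serotonin). Each was compared with a wild type carrying the same epidermal reporter transgene, at n = 3 libraries per group and 29.8 to 38.8 M reads per library.

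Transcripts of the mutated genes were examined first. The tbh-1 transcript (WBGene00006541) was nearly absent from tbh-1 mutants, at 5.82 ± 0.18 CPM against 256 ± 5.57 CPM in wild type, a 44.0-fold fall (adjusted p = 2.19e-19, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The tph-1 transcript (WBGene00006600) fell in tph-1 mutants from 57 to 9 reads over 3 libraries, a log2 change of -2.78 (SE 0.452, adjusted p = 0.00061). The cat-2 transcript (WBGene00000296) was at 0.474 ± 0.0768 CPM in cat-2 mutants and 0.843 ± 0.27 CPM in wild type and did not pass the test (log2 change -0.83, adjusted p = 0.0811). That call turned on wild type replicate 3, without which the change was -1.03 (adjusted p = 0.0498). The tdc-1 transcript (WBGene00006562) did not pass the test in tdc-1 mutants, at 201 ± 0.789 CPM against 209 ± 9.54 CPM (log2 change -0.06, adjusted p = 0.276), so the counts do not check the genotype of that strain. In tdc-1 mutants tbh-1, which encodes the next enzyme of the pathway, rose by a log2 change of 0.19 (SE 0.0428, adjusted p = 0.00445, and 0.0602 without replicate 1). In tbh-1 mutants tdc-1 rose by 0.21 (SE 0.0418, adjusted p = 0.00853), a call lost with only the 2 groups compared (0.061), without wild type replicate 1 (0.05002), and without replicate 1 (0.105) or 3 (0.178) of all groups.

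**Figure D1:**
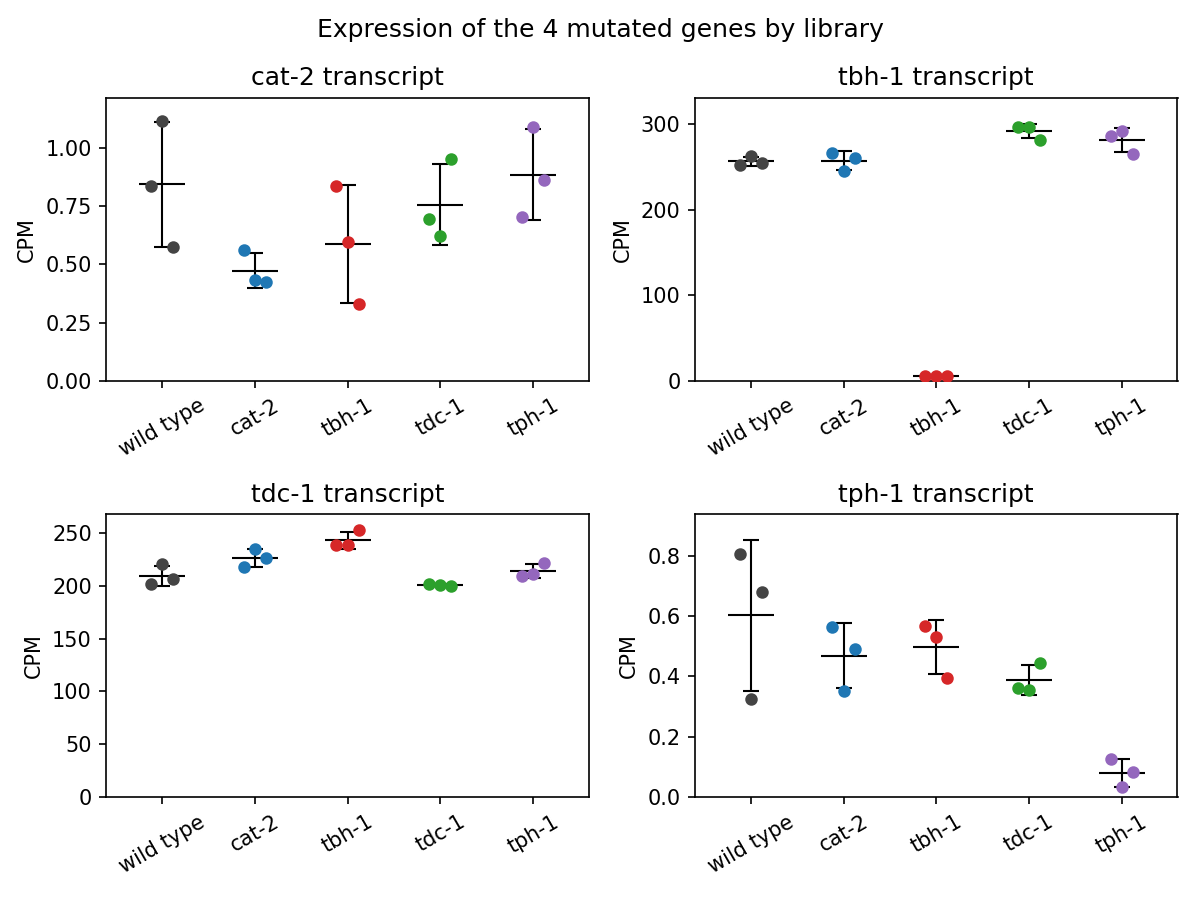
Level of the 4 mutated genes in each library (CPM) by genotype. Each point is 1 library, with the mean and SD of n = 3.

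In cat-2 mutants, genes of the epidermal antimicrobial peptide family fell. The caenacin gene cnc-8 fell from 20.0 ± 1.09 to 7.16 ± 0.277 CPM (log2 change -1.48, SE 0.0704, adjusted p = 8.69e-10) and nlp-33 from 11.6 ± 0.634 to 1.47 ± 0.313 CPM (-2.97, SE 0.194, adjusted p = 3.55e-08). Of 16 family members, 8 fell and 8 did not pass (8 adjusted over the list alone; camera adjusted p = 1.10e-09, adjusted p = 0.0735 with an estimated correlation). Detoxification genes fell too. Among 63 UDP-glucuronosyltransferase genes, 29 fell, 4 rose and 30 did not pass (35 and 5 adjusted over the list alone; camera adjusted p = 1.10e-09, adjusted p = 0.329 with an estimated correlation), including ugt-63 (35.2 ± 4.16 to 3.23 ± 1.43 CPM, adjusted p = 3.48e-07) and ugt-12 (log2 change -2.04, adjusted p = 1.92e-09). Among 58 cytochrome P450 genes, 24 fell and 5 rose (25 and 5 adjusted over the list alone; camera adjusted p = 5.33e-05, adjusted p = 0.329 with an estimated correlation), with cyp-14A1 at -3.27 and cyp-25A3 at -1.91.

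Muscle and cuticle genes were lower in cat-2 mutants. The troponin T gene tnt-2 fell from 411 ± 23.2 to 191 ± 35.2 CPM (log2 change -1.11, SE 0.118, adjusted p = 2.15e-05), the thin filament gene unc-87 by -0.71 and the troponin C gene pat-10 by -0.60. Of 32 muscle genes 21 fell and 11 did not pass (23 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.10e-09, adjusted p = 0.402 with an estimated correlation). Cuticle collagens col-95 (-2.53), col-101 (-2.85) and col-80 (-2.80) fell, as did 44 of 129 collagens against 7 that rose (46 and 7 adjusted over the list alone; camera adjusted p = 1.03e-10, adjusted p = 0.402 with an estimated correlation). The 7 became 4 without wild type replicate 1 or cat-2 replicate 2, and 3 without wild type replicate 3. Fatty acid desaturase genes fat-5 (89.5 ± 13.6 to 17.2 ± 2.17 CPM, adjusted p = 5.2e-06) and fat-7 (-0.81, adjusted p = 0.000634) fell, and 9 of 19 fatty acid enzyme genes fell against 1 that rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.00441, adjusted p = 0.357 with an estimated correlation). Yolk protein genes vit-1 (-0.37, adjusted p = 0.000689) and vit-3 (-0.64, adjusted p = 0.00229) fell, and 3 of 6 vitellogenins passed (4 adjusted over the list alone; camera adjusted p = 0.0746).

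Genes that rose in cat-2 mutants included defense genes. The lysozyme gene ilys-3 rose from 0.491 ± 0.325 to 3.35 ± 0.127 CPM (log2 change 2.78, SE 0.318, adjusted p = 9.79e-06), with lys-10 at 2.81 and lys-7 at 0.87. Of 35 lysozyme and saposin-like genes 10 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.000478, adjusted p = 0.445 with an estimated correlation), and 6 rose without cat-2 replicate 2 or without wild type replicate 3. In the list of intracellular pathogen response genes, which respond to microsporidia and virus, 8 of 21 rose and 13 did not pass (8 adjusted over the list alone; camera adjusted p = 0.000138, adjusted p = 0.329 with an estimated correlation), among them B0507.8 (0.716 ± 0.0915 to 6.45 ± 1.97 CPM), pals-26 (1.64) and eol-1 (1.36). The largest rise with a tight spread was nspe-7, from 0.438 ± 0.13 to 7.44 ± 1.19 CPM (4.07, adjusted p = 1.92e-09). Other defense genes fell: of 143 C-type lectins 57 fell and 12 rose (60 and 12 adjusted over the list alone; camera adjusted p = 0.0108, adjusted p = 0.606 with an estimated correlation), with clec-146 at -2.14. Germ line groups moved in opposite directions. Sperm genes fell in 41 of 59 cases against 1 that rose (44 and 1 adjusted over the list alone; camera adjusted p = 6.01e-07, adjusted p = 0.606 with an estimated correlation), for example spe-26 (-1.23) and msp-152 (-2.12). The count of 41 became 26 without wild type replicate 1, 20 without wild type replicate 3, 17 without cat-2 replicate 2 and 20 without cat-2 replicate 3.

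Among oocyte and eggshell genes, pos-1 (0.21, SE 0.0357, adjusted p = 0.000646) and mex-6 (0.17, SE 0.035, adjusted p = 0.00274) rose in cat-2 mutants. Of 39 listed genes 13 rose (13 adjusted over the list alone, with 1 lower; camera adjusted p = 0.000138, adjusted p = 0.606 with an estimated correlation). That count was 21 with the replicate block, 4 without wild type replicate 1, 6 without wild type replicate 3, and 22, 5 and 4 without cat-2 replicates 1, 2 and 3. Within the amine synthesis list, pcbd-1 (22 ± 0.668 to 11.1 ± 0.241 CPM, adjusted p = 2.04e-08) and qdpr-1 (-0.40, adjusted p = 2.74e-05), whose products recycle the pterin cofactor of the hydroxylases, fell. The phenylalanine hydroxylase gene pah-1 also fell (-0.44, adjusted p = 0.000487), and of 26 listed genes 6 fell and 2 rose (6 and 4 adjusted over the list alone; camera adjusted p = 0.296). Of 20 amine receptor genes ser-7 (-0.55, adjusted p = 0.0128) and ser-3 (-0.43, adjusted p = 0.0249) passed. Both receptor calls were lost without wild type replicate 1 (0.0733 and 0.11) and without cat-2 replicate 2 (0.0746 and 0.104), and ser-3 also without wild type replicate 3 (0.0667) and cat-2 replicate 3 (0.102).

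Over all genes, 3719 of 15863 changed in cat-2 mutants, 1182 higher and 2537 lower, and 178 and 1044 of these by more than 2-fold. Over all tested genes the CPM ranges of the groups did not overlap for 36.8%, against 10% by chance. The count fell to 2258 without wild type replicate 1, 2318 without cat-2 replicate 2 and 2402 without cat-2 replicate 3. The 1182 higher genes became 1941 with the replicate block, 2180 without cat-2 replicate 1 and 737 without wild type replicate 3.

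**Figure D2:**
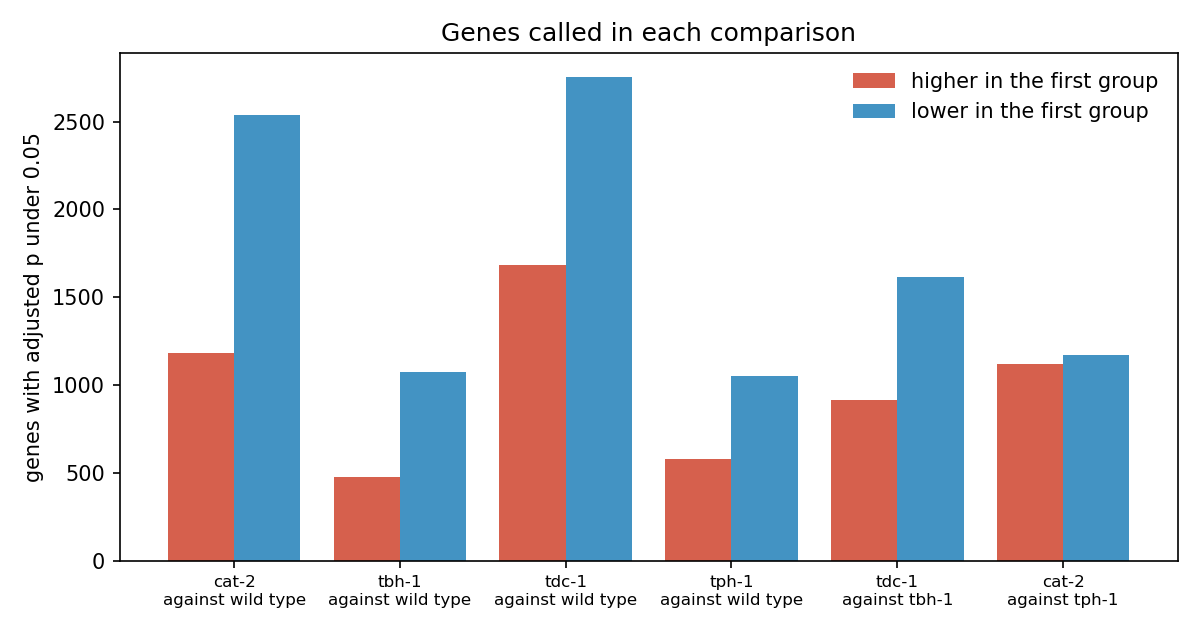
Number of genes past an adjusted p of 0.05 in each comparison (edgeR quasi-likelihood test), split into higher and lower. Each comparison used 3 libraries per group.

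In tbh-1 mutants, a second transcript was missing. Y102A5C.36, on chromosome V, had 705 reads in wild type (7.35 ± 0.343 CPM) and 0 in tbh-1 mutants, at least 235-fold lower. The gene B0511.11 rose from 3.82 ± 0.686 to 22.7 ± 1.16 CPM (log2 change 2.58, SE 0.111, adjusted p = 2.21e-10), C46G7.5 by 2.08 (SE 0.151, adjusted p = 3.54e-07) and thn-1 by 1.18 (SE 0.126, adjusted p = 3.76e-05). The peptide transporter gene pept-2 fell from 116 ± 4.93 to 35.7 ± 1.76 CPM (-1.70, SE 0.0648, adjusted p = 3.79e-11) and scl-24 by -4.12 (SE 0.418, adjusted p = 3.91e-05). In the amine synthesis list, which holds tbh-1 itself, 5 of 26 genes fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 3.77e-11, adjusted p = 0.0165 with an estimated correlation). Without the 4 mutated genes that result was lost, with 4 of 22 genes lower (camera adjusted p = 0.339, adjusted p = 0.884 with an estimated correlation). The 5 became 3 without tbh-1 replicate 2 or wild type replicate 2 or 3, and 2 without tbh-1 replicate 3 or wild type replicate 1.

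Sperm genes and C-type lectins were lower in tbh-1 mutants. The major sperm protein gene msp-152 fell by -2.22 (SE 0.405, adjusted p = 0.00715), and 36 of 59 sperm genes fell while 23 did not pass (47 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.85e-14, adjusted p = 0.785 with an estimated correlation). The 36 became 3 without wild type replicate 1, 8 without wild type replicate 3, 7 without tbh-1 replicate 2 and 8 without tbh-1 replicate 3. Lectin genes fell in 36 of 143 cases against 2 that rose (40 and 3 adjusted over the list alone; camera adjusted p = 7.44e-05, adjusted p = 0.785 with an estimated correlation), with clec-190 at -2.64 and, in the other direction, clec-97 at 0.60. Those 36 became 11 and 19 without wild type replicates 1 and 3, and 18 and 23 without tbh-1 replicates 2 and 3. Of 129 collagens 21 fell (37 adjusted over the list alone; camera adjusted p = 1.32e-07, adjusted p = 0.785 with an estimated correlation), a count of 35 with DESeq2, of 1 and 4 without wild type replicates 1 and 3, and of 6 without tbh-1 replicate 3. Of 32 muscle genes 7 fell, or 18 with DESeq2 and 0 without wild type replicate 1 or 3 or tbh-1 replicate 3. Of 39 oocyte and eggshell genes 6 rose and 1 fell, or 13 and 1 with DESeq2 and 1 and 0 without wild type replicate 1 or 3.

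The total for tbh-1 was 1554 genes, 478 higher and 1076 lower, with 14 and 624 past 2-fold and group ranges apart for 26.8% of all tested genes (10% by chance). It depended on single libraries more than any other comparison with wild type. Without wild type replicates 1 and 3 it was 271 and 458, without tbh-1 replicates 2 and 3 it was 694 and 503, and with the replicate block it was 2679 (1076 higher and 1603 lower). It was 136 with only the 2 groups compared. The 478 higher genes became 757 with DESeq2 and 764 without tbh-1 replicate 1.

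In tdc-1 mutants, genes of protein turnover changed in opposite directions. The proteasome subunit gene pas-7 rose from 177 ± 3.34 to 207 ± 2.02 CPM (log2 change 0.23, SE 0.0382, adjusted p = 0.000428) and rpn-5 by 0.20 (SE 0.0365, adjusted p = 0.000922), and 25 of 33 subunit genes rose while 8 did not pass (28 adjusted over the list alone; camera adjusted p = 1.06e-08, adjusted p = 0.361 with an estimated correlation). Ubiquitin pathway genes ubc-13 (0.20) and ufd-1 (0.15) rose, 11 of 33 in that list (11 adjusted over the list alone; camera adjusted p = 0.00115, adjusted p = 0.33 with an estimated correlation), or 7 without wild type replicate 1 and 17 with DESeq2 and with its size factors. F-box and BTB-MATH genes, whose products are thought to choose substrates for ubiquitin ligases, fell more often than they rose: fbxb-10 from 4.14 ± 0.29 to 0.796 ± 0.176 CPM (adjusted p = 1.92e-06), fbxb-72 by -2.04 and fbxa-72 by -1.46. Of 314 such genes 100 fell, 17 rose and 197 did not pass (124 in either direction adjusted over the list alone, 20 of them higher; camera adjusted p = 0.00227, adjusted p = 0.58 with an estimated correlation). Without wild type replicates 1 and 3 the 17 became 11 and 10. Against that direction math-26 rose from 1.82 ± 0.183 to 8.66 ± 1.02 CPM (adjusted p = 6.58e-09) and fbxb-14 by 3.19 (SE 0.405).

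**Figure D3:**
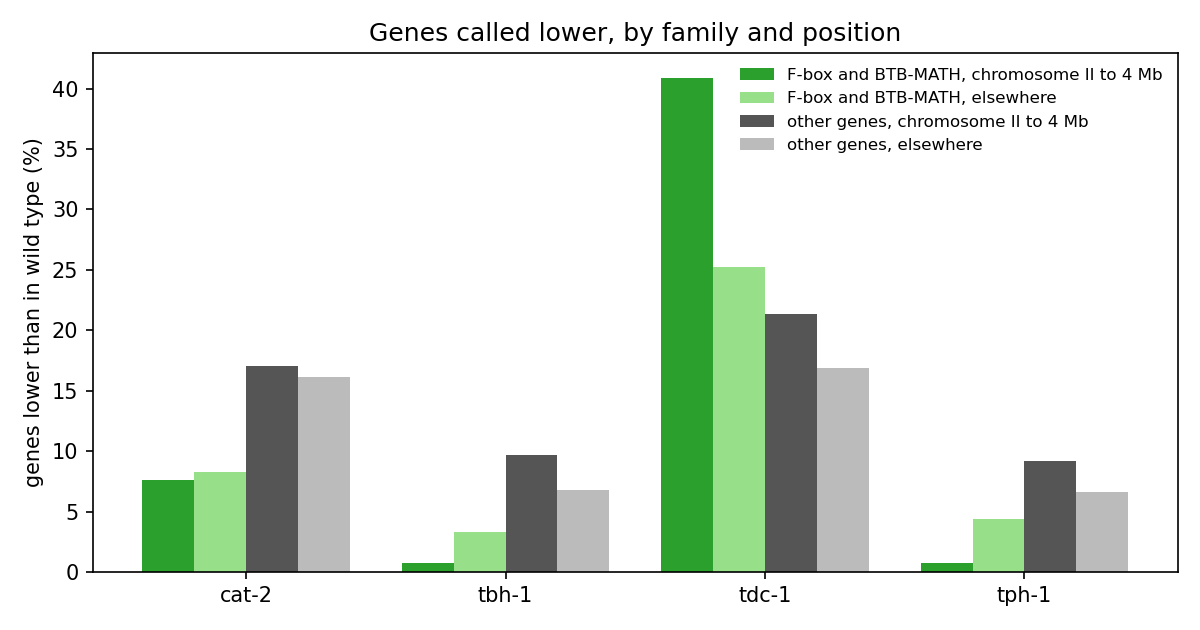
Percent of genes lower than in wild type in each mutant (adjusted p under 0.05, edgeR quasi-likelihood test, n = 3 libraries per group). Bars part F-box and BTB-MATH genes from other genes, each inside the first 4 Mb of chromosome II and elsewhere.

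Muscle, cuticle and detoxification genes fell in tdc-1 mutants. The gene tnt-2 fell from 411 ± 23.2 to 222 ± 14.1 CPM (-0.89, SE 0.117, adjusted p = 0.00013) and unc-87 by -0.65, and 24 of 32 muscle genes fell against 1 that rose (25 and 1 adjusted over the list alone; camera adjusted p = 8.74e-08, adjusted p = 0.508 with an estimated correlation). Collagens col-95 (-2.31) and col-101 (-2.74) were among 42 that fell of 129, against 7 that rose (47 and 9 adjusted over the list alone; camera adjusted p = 8.74e-08, adjusted p = 0.524 with an estimated correlation). For UDP-glucuronosyltransferases 35 of 63 fell and 3 rose (35 and 3 adjusted over the list alone; camera adjusted p = 3.20e-09, adjusted p = 0.33 with an estimated correlation), with ugt-63 at -3.60 and ugt-12 at -1.99. Of 58 cytochrome P450 genes 22 fell and 5 rose (25 and 7 adjusted over the list alone; camera adjusted p = 6.27e-05, adjusted p = 0.329 with an estimated correlation), with cyp-25A3 at -2.06. Antimicrobial peptide genes cnc-8 (-1.53) and nlp-33 (-2.78) were among 8 of 16 that fell (10 adjusted over the list alone; camera adjusted p = 3.99e-10, adjusted p = 0.0621 with an estimated correlation). The desaturase gene fat-5 fell by -2.63, and 9 of 19 fatty acid enzyme genes fell (10 adjusted over the list alone; camera adjusted p = 0.00187, adjusted p = 0.359 with an estimated correlation).

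Oocyte and eggshell genes rose in tdc-1 mutants. The RNA-binding protein genes pos-1 (0.21, SE 0.0357, adjusted p = 0.000499), spn-4 (0.25), cey-3 (0.22) and mex-6 (0.18) rose, with 26 of 39 in the list (31 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.78e-08, adjusted p = 0.508 with an estimated correlation). The 26 became 13 and 15 without wild type replicates 1 and 3. In the intracellular pathogen response list 6 of 21 genes rose (6 adjusted over the list alone; camera adjusted p = 0.0124, adjusted p = 0.366 with an estimated correlation), B0507.8 by 2.92 (SE 0.408, adjusted p = 0.000194). The pterin gene pcbd-1 fell by -0.96 (SE 0.0639, adjusted p = 2.84e-08) and pah-1 by -0.62 (SE 0.0731, adjusted p = 1.52e-05). Among amine receptors ser-3 was at -0.50 (adjusted p = 0.0097), a call lost without wild type replicate 1 (0.0518) and tdc-1 replicate 2 (0.0505). Of 59 sperm genes 1 fell and 2 rose (camera adjusted p = 0.998), although 49 had a negative change with a median of -0.51, and 15 fell without wild type replicate 2. Of 6 vitellogenins 1 fell (camera adjusted p = 0.98), a call lost without any 1 of the 6 libraries.

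In total 4434 genes changed in tdc-1 mutants, 1681 higher and 2753 lower, with 112 and 774 past 2-fold and group ranges apart for 45.5% of all tested genes (10% by chance). The split by direction depended on the setting. With DESeq2 size factors 2357 were higher and 2513 lower. With only the 2 groups compared the larger part turned, with 2698 higher and 2465 lower. Without wild type replicate 1 there were 1077 higher, and without tdc-1 replicate 2 there were 1805 lower.

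In tph-1 mutants, defense genes moved in both directions. The intracellular pathogen response genes B0507.8 (log2 change 3.21, SE 0.403, adjusted p = 0.00017), B0507.6 (1.36, SE 0.204, adjusted p = 0.000297) and eol-1 (1.33, SE 0.171, adjusted p = 7.49e-05) rose, with 9 of 21 in the list (10 adjusted over the list alone; camera adjusted p = 1.58e-09, adjusted p = 0.0739 with an estimated correlation). Of 28 intestinal pathogen response genes 4 rose (6 adjusted over the list alone, 8 with the replicate block; camera adjusted p = 0.00088, adjusted p = 0.686 with an estimated correlation), including C17H12.8 (253 ± 17.8 to 419 ± 41.7 CPM) and dod-22 (1.44). The lysozyme gene lys-7 rose by 0.86 (SE 0.129, adjusted p = 0.000727), and 7 of 35 lysozyme and saposin-like genes rose (9 adjusted over the list alone; camera adjusted p = 0.00238, adjusted p = 0.686 with an estimated correlation), or 3 and 2 without wild type replicates 1 and 3 and 3 and 2 without tph-1 replicates 2 and 3. Antimicrobial peptide genes cnc-8 (-0.93) and nlp-28 (-2.12) fell, 6 of 16 in that list (6 adjusted over the list alone; camera adjusted p = 8.18e-05, adjusted p = 0.369 with an estimated correlation). Lectins fell in 40 of 143 cases against 8 that rose (46 and 13 adjusted over the list alone; camera adjusted p = 0.00238, adjusted p = 0.697 with an estimated correlation), with the 8 at 5 without wild type replicate 1 or tph-1 replicate 3, led by clec-137, which went from 546 to 7 reads (-6.39, SE 0.777, adjusted p = 0.00016).

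Within amine synthesis in tph-1 mutants, the decarboxylase gene bas-1, which acts after tph-1, rose from 10.7 ± 0.548 to 14.2 ± 0.714 CPM (0.41, SE 0.0755, adjusted p = 0.00187). The pterin gene pcbd-1 fell (-0.66, SE 0.0627, adjusted p = 4.16e-06), and 7 of 26 listed genes rose and 4 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.653). The 7 became 4 without tph-1 replicate 2. Detoxification genes ugt-63 (-3.09), ugt-12 (-1.47) and cyp-14A1 (-2.53) fell. For UDP-glucuronosyltransferases 15 of 63 fell and 8 rose (18 and 8 adjusted over the list alone; camera adjusted p = 0.00936, adjusted p = 0.697 with an estimated correlation). The 8 that rose became 5, 3 and 2 without wild type replicates 1, 2 and 3, and 2, 4 and 3 without tph-1 replicates 1, 2 and 3. For cytochrome P450 genes 16 of 58 fell and 6 rose (17 and 8 adjusted over the list alone; camera adjusted p = 0.022, adjusted p = 0.686 with an estimated correlation). The desaturase genes fat-7 (-0.90) and fat-5 (-1.06) were among 7 of 19 fatty acid enzyme genes that fell (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00238, adjusted p = 0.686 with an estimated correlation), or 3 without wild type replicate 1 and 4, 3 and 4 without tph-1 replicates 1, 2 and 3. The yolk protein gene vit-1 fell by -0.35 (adjusted p = 0.00182), and 2 of 6 vitellogenins fell (3 adjusted over the list alone, 3 with the replicate block; camera adjusted p = 0.0164, adjusted p = 0.686 with an estimated correlation). The 2 became 1 without any 1 of the tph-1 libraries or without wild type replicate 2 or 3, and 3 without wild type replicate 1. The adaptor gene math-26 rose from 1.82 ± 0.183 to 9.89 ± 1.32 CPM (2.44, adjusted p = 6.98e-09). Of 32 muscle genes 1 fell, a call lost without wild type replicate 1 and without tph-1 replicate 1 or 3.

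Sperm genes fell in 8 of 59 cases in tph-1 mutants (34 adjusted over the list alone; camera adjusted p = 1.44e-06, adjusted p = 0.697 with an estimated correlation), 14 with DESeq2. That count was 1, 36 and 1 without wild type replicates 1, 2 and 3, and 3, 3 and 1 without tph-1 replicates 1, 2 and 3. For replicate number 2 the list mean was higher in tph-1 than in wild type (0.488 against 0.302 mean log2 CPM), and it was lower for numbers 1 and 3. In total 1629 genes changed in tph-1 mutants, 577 higher and 1052 lower, with 199 and 451 past 2-fold and group ranges apart for 26% of all tested genes (10% by chance). Without wild type replicate 1 it was 1063. Without tph-1 replicate 3 there were 692 lower.

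**Figure D4:**
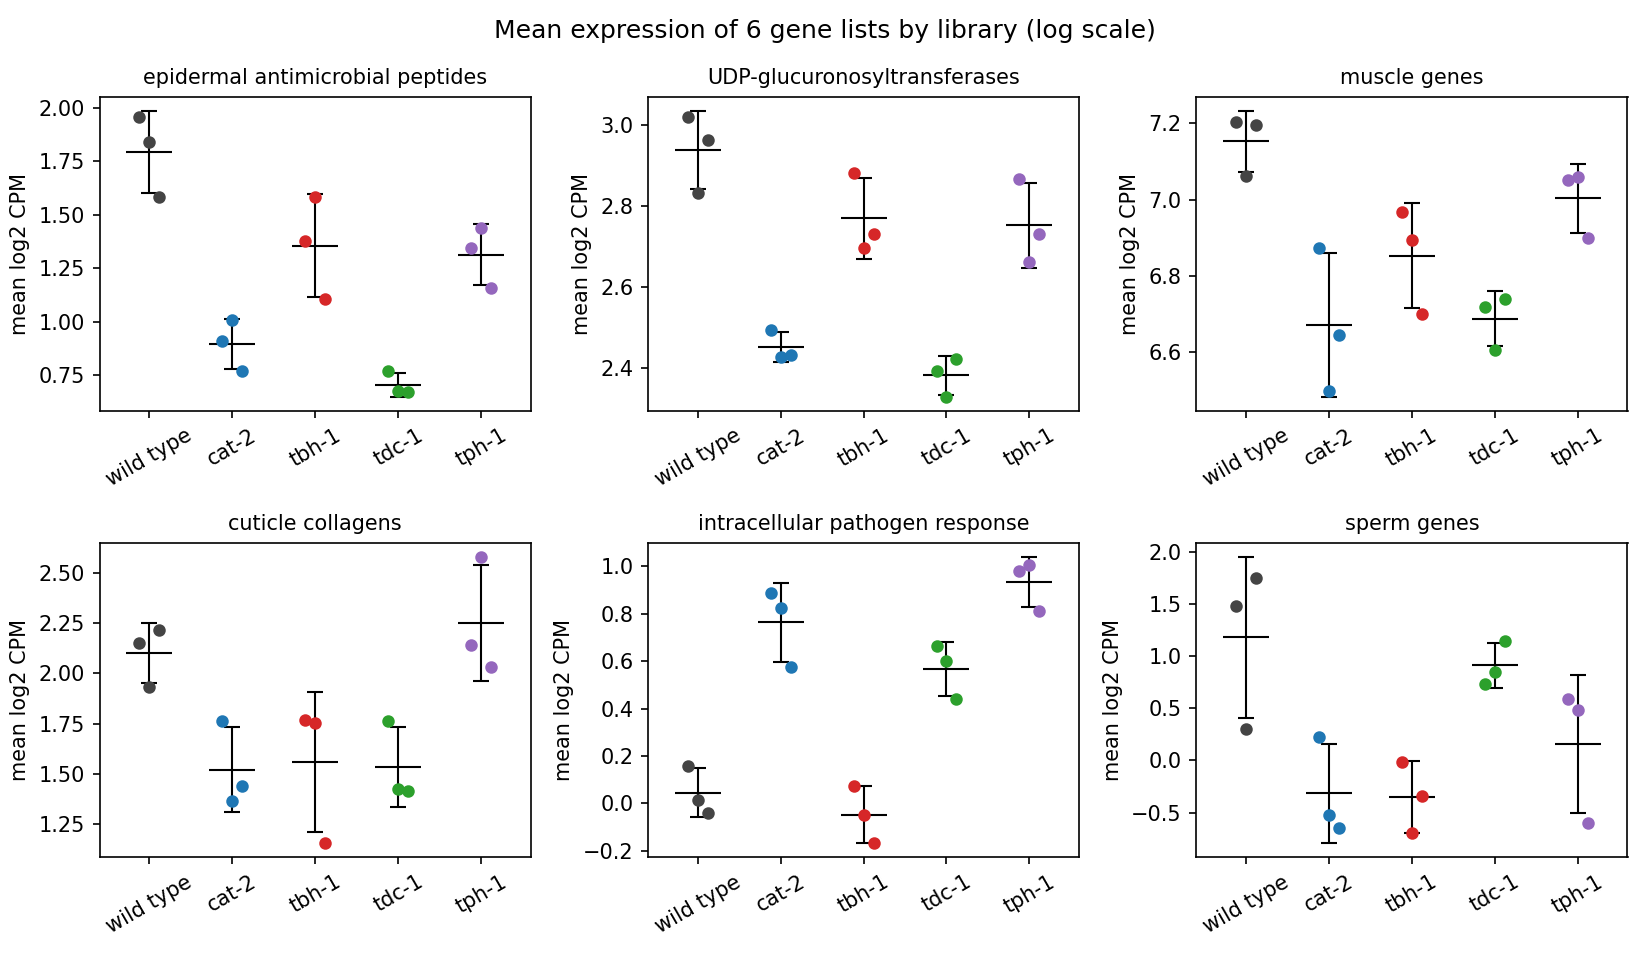
Mean log2 CPM of 6 gene lists by genotype. Each point is 1 library, with the mean and SD of n = 3 per genotype.

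Octopamine synthesis needs both tdc-1 and tbh-1, and tyramine synthesis needs tdc-1 alone, although no amine was measured in these animals. Compared directly, tdc-1 mutants had more tbh-1 transcript (log2 change 5.65, SE 0.0578, adjusted p = 1.35e-19), less tdc-1 transcript (-0.28, SE 0.0418, adjusted p = 0.000202) and 858 reads of Y102A5C.36 against 0, at least 271-fold more. Detoxification and antimicrobial genes were lower in tdc-1 mutants: ugt-63 (-3.96), ugt-12 (-1.75), cyp-25A3 (-1.93), nlp-33 (-2.67) and cnc-8 (-1.39). Of UDP-glucuronosyltransferases 23 were lower and 5 higher of 63 (27 and 8 adjusted over the list alone; camera adjusted p = 1.48e-06, adjusted p = 0.432 with an estimated correlation). Of cytochrome P450 genes 20 were lower and 3 higher of 58 (20 and 4 adjusted over the list alone; camera adjusted p = 7.87e-05, adjusted p = 0.214 with an estimated correlation), and 8 of 16 antimicrobial peptide genes were lower (9 lower and 2 higher adjusted over the list alone; camera adjusted p = 1.48e-06, adjusted p = 0.145 with an estimated correlation). F-box and BTB-MATH genes were lower in 93 of 314 cases and higher in 7 (107 and 8 adjusted over the list alone; camera adjusted p = 3.01e-06, adjusted p = 0.432 with an estimated correlation), with fbxb-10 at -2.09 and math-26, in the other direction, at 2.47. The pathogen response gene B0507.8 was higher in tdc-1 (2.94, adjusted p = 0.000256), with 6 of 21 in its list (8 adjusted over the list alone; camera adjusted p = 0.00914, adjusted p = 0.432 with an estimated correlation).

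Sperm genes were higher in tdc-1 than in tbh-1 mutants, msp-152 by 1.93 (SE 0.41, adjusted p = 0.00444) and 18 of 59 in the list (33 adjusted over the list alone; camera adjusted p = 6.62e-09, adjusted p = 0.584 with an estimated correlation). DESeq2 gave 31. The 18 became 11, 5 and 4 without tbh-1 replicates 1, 2 and 3, and 8 and 5 without tdc-1 replicates 2 and 3. Lectins were higher in 39 of 143 cases and lower in 12 (44 and 13 adjusted over the list alone; camera adjusted p = 0.00269, adjusted p = 0.587 with an estimated correlation), clec-141 by 2.76, and the 39 became 22 without tdc-1 replicate 3 and 19 without tbh-1 replicate 2. The 12 became 6 without tdc-1 replicate 1 or tbh-1 replicate 1, and 7 without tbh-1 replicate 2. In total 2529 genes differed, 916 higher and 1613 lower in tdc-1, with 444 and 565 past 2-fold and group ranges apart for 33.7% of all tested genes (10% by chance). The 916 became 575 without tdc-1 replicate 3 and 586 without tbh-1 replicate 3.

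Between cat-2 and tph-1 mutants the clearest difference was in dhcr-24, which encodes a sterol reductase, at 3.25 ± 0.439 CPM in cat-2 and 20.8 ± 1.51 CPM in tph-1 (log2 change -2.67, SE 0.11, adjusted p = 6.46e-10). The pterin synthesis gene ptps-1 (-0.53, SE 0.0897, adjusted p = 0.00153) and bas-1 (-0.50, SE 0.0753, adjusted p = 0.000664) were lower in cat-2, and the lysozyme genes ilys-3 (1.97) and lys-10 (2.49) were higher. Collagens col-80 (204 ± 35.6 against 513 ± 49.4 CPM) and col-8 (481 ± 61.9 against 906 ± 43.6 CPM) were lower in cat-2, with 45 of 129 in the list (60 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.18e-18, adjusted p = 0.198 with an estimated correlation), or 26 without cat-2 replicate 3. Muscle genes tnt-2 (-0.77) and unc-87 (-0.58) were among 19 of 32 that were lower (21 adjusted over the list alone; camera adjusted p = 3.19e-09, adjusted p = 0.292 with an estimated correlation), or 6 and 5 without cat-2 replicates 2 and 3 and 5 and 7 without tph-1 replicates 1 and 2. Oocyte genes mex-6 (0.24) and pos-1 (0.23) were higher, with 18 of 39 (29 adjusted over the list alone, 32 with the replicate block; camera adjusted p = 6.97e-12, adjusted p = 0.249 with an estimated correlation), or 6 and 9 without cat-2 replicates 2 and 3 and 5 without tph-1 replicate 1. Of UDP-glucuronosyltransferases 14 of 63 were lower (26 adjusted over the list alone, 27 with the replicate block; camera adjusted p = 2.31e-07, adjusted p = 0.198 with an estimated correlation), among them ugt-9 (-1.19) and ugt-66 (-1.53). The antimicrobial genes nlp-33 (-1.94) and cnc-8 (-0.55) were lower, 6 of 16 in that list (6 adjusted over the list alone; camera adjusted p = 0.000135, adjusted p = 0.198 with an estimated correlation).

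The count between cat-2 and tph-1 was 2290, 1118 higher and 1172 lower in cat-2, with 54 and 155 past 2-fold and group ranges apart for 33.2% of all tested genes (10% by chance). It was 993 and 957 without cat-2 replicates 2 and 3, 915 and 1477 without tph-1 replicates 1 and 3, and 3718 with the replicate block. The larger part turned with the replicate block (1998 higher and 1720 lower), DESeq2 (1393 and 1157) and its size factors (1129 and 1123). Higher genes numbered 679 without tph-1 replicate 2 and 693 with a mean of at least 5 CPM.

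Several genes changed the same way in all 4 mutants. The gene rdl-1 rose by log2 changes of 2.46, 2.4, 2.44 and 2.33 in cat-2, tbh-1, tdc-1 and tph-1, and B0511.11 by 1.33, 2.58, 1.72 and 2.25. The transporter gene pept-2 fell by -0.55, -1.70, -1.76 and -1.55, and the dual oxidase gene bli-3, whose product takes part in cross-linking the cuticle, by -0.73, -0.52, -0.82 and -0.46. In all 4 mutants 10 genes rose and 126 fell, and 1344 genes changed in the same direction in at least 3, of which 340 rose and 1004 fell. That count was 648 without wild type replicate 1, 803 without wild type replicate 3 and 2068 with the replicate block. The 340 that rose became 754 without cat-2 replicate 1. Between cat-2 and tdc-1, 734 genes rose and 1622 fell in both, against 125 and 440 for independent sets. Between tbh-1 and tph-1, 376 fell in both against 71.4. In the same pair 19 rose in both against 17.4, and 33 moved in opposite directions. Fold changes correlated at 0.698 for cat-2 and tdc-1, 0.79 for cat-2 and tph-1, 0.635 for cat-2 and tbh-1 and 0.595 for tbh-1 and tph-1. They correlated at 0.461 for tdc-1 and tph-1 and 0.306 for tbh-1 and tdc-1. The shared controls alone gave 0.502 to 0.513 in simulation, where mutants had no changes of their own. Changes that differ between mutants can lower a correlation below that level. Rank correlations ran from 0.328 (tbh-1 and tph-1) to 0.742 (cat-2 and tdc-1), with 0.514 for tbh-1 and tdc-1. Covariances exceeded the simulated ones by 0.0715 (tbh-1 and tdc-1) to 0.299 (cat-2 and tph-1). All 4 comparisons used the same 3 wild type libraries, which cannot be split, so part of the sharing belongs to those controls, and genes are not independent replicates. The control was also a single strain. A gene that differs only in that strain would change the same way in all 4 mutants, as rdl-1 did, and the design cannot tell this apart.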

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

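Tests on tissue shares, on the wild type libraries and on F-box genes were chosen only after the result was seen. In tdc-1 mutants oocyte genes rose while muscle and collagen genes fell, which a higher share of germ line RNA against all somatic RNA would also give. As the only cause, that explanation needs all somatic genes to fall alike, but the median change of 32 muscle genes was -0.57 and that of 49 intestinal and neuronal genes -0.14. The difference was -0.44, and by replicate number the means of the lists differed by -0.31, -0.36 and -0.39. These values argue against an equal fall of all somatic RNA as the only cause. Of 23 intestinal genes 9 fell and 2 rose. A larger germ line share beside changes of single tissues would also give unequal falls, so it stays open, as does a lower share of muscle RNA. All groups were collected as adults, 48 h after the L4 stage. A different age at harvest would move collagens and molting genes together, with molting genes at 0.5 or more of the collagen fall in every pair. This comparison does not tell younger from older animals. The median of 23 molting genes was -0.22, and the pairs gave -0.167 against -0.388, -0.254 against -0.511 and -0.394 against -0.800, each under that bound but by a mean smaller than its spread, so the question stays open.

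The number of sperm genes lower in cat-2 and tbh-1 mutants could depend on spread among the wild type libraries. Of 41 sperm genes lower in cat-2, 26, 41 and 20 were still called without wild type replicates 1, 2 and 3, and of 36 in tbh-1, 3, 36 and 8. With all libraries the median change of the list was -2.05 and -2.04. In the same omissions it was -2.03, -2.38 and -1.64 in cat-2 and -1.96, -2.45 and -1.60 in tbh-1. Each omission kept wild type replicate 1 or 3, the controls with the higher list means (1.48 and 1.75 mean log2 CPM). Wild type replicate 2 was at 0.302, near cat-2 replicate 1 (0.227), and its summed sperm level of 267 CPM lay just below that library (268). The tbh-1 libraries were lower (-0.0137, -0.695 and -0.338 mean log2 CPM). Calls were also lost without cat-2 replicate 2 (17) or 3 (20), and dropping a library lowers power. Without wild type replicate 2, however, all sperm genes called lower numbered 45 in cat-2 and 46 in tbh-1. A loss of power alone would not raise these counts, so the number depended on which controls were kept. How much of it belongs to control spread stays open, and the lost calls are no evidence against the fall. Reads shared between near-identical msp and ssp genes would leave other sperm genes unmoved, but these had medians of -0.73 in cat-2 and -1.03 in tbh-1. That argues against shared reads as the only source of the fall. Lower calls were 29 of 32 msp and ssp genes against 12 of 27 others in cat-2, and 24 of 32 against 12 of 27 in tbh-1. Shared reads can repeat a signal over several genes, so their part in the number stays open.

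Lower F-box and BTB-MATH genes in tdc-1 mutants could reflect a difference of the strain on the left part of chromosome II, where the family is dense and 40.9% of 132 members fell. Outside that part 25.3% of members fell against 16.9% of other genes (Fisher p = 0.00516), which argues against the region as the only cause. Inside it 21.4% of 599 other genes fell, also above the 16.9% elsewhere (Fisher p = 0.00557), so a part of the region stays open. Both Fisher tests treat genes as independent, which paralogs in clusters are not. Reads moved between paralogs within the interval would leave their total unchanged, but the summed level of members in the interval was 87.5% of wild type (556 ± 8.24 against 635 ± 18.5 CPM). Members outside it were not summed, so reads moved to them were not tested.

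Opposite and different changes were found for 18 genes between tdc-1 and tbh-1 and for 18 genes between cat-2 and tph-1. The difference was tested mutant against mutant, and the genes named here were chosen after their values were seen, except tbh-1 and cyp-13A2. Besides tbh-1, F44E2.4 rose in tdc-1 and fell in tbh-1 (-0.52, adjusted p = 0.048; difference 1.57, adjusted p = 1.44e-06), as did H03E18.1 (0.91 and -0.62). The histone genes his-68 (difference 0.77) and hil-5 (0.45 and -0.15) rose in cat-2 and fell in tph-1, and cyp-13A2 did the reverse (-0.77 and 0.38; difference -1.14, adjusted p = 1.93e-05).

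Of the 10 ways to part the 6 libraries of a comparison into 3 and 3, the real one was the only 1 to reach its count in each of the 6 comparisons. Every other split called 0 genes. At unadjusted p under 0.05 the real and the highest other split gave 5721 and 2968 (cat-2), 4159 and 3084 (tbh-1), 6313 and 1631 (tdc-1), 3650 and 1612 (tph-1), 4552 and 1164 (tdc-1 with tbh-1), and 4883 and 2265 (cat-2 with tph-1). Splits that part all 3 replicate pairs, as the real one does, reached at most 978, 1132, 565, 1330, 787 and 883 in that order. Each other split mixed libraries of both genotypes within its groups, so any real difference between them added to the spread. Its 0 calls are therefore no estimate of calls by chance, and 10 splits are too few for a share under 0.05.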

How the results depend on the processing

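Tests on gene list counts without each library and on the amine synthesis list without the mutated genes were chosen only after the result was seen. Counts fell with a mean of at least 5 CPM, where fewer genes were tested: 2241 (cat-2), 720 (tbh-1), 650 (tph-1), 1418 (tdc-1 with tbh-1) and 665 (shared by at least 3 mutants). With only the 2 groups compared, tbh-1 had 136 genes (24 higher and 112 lower) and the shared count was 684. Fewer samples estimated the spread there, but this alone does not explain the fall, since tdc-1 rose to 5163 genes. The same setting gave 2599 (cat-2), 1213 (tph-1), 2505 (tdc-1 with tbh-1) and 1749 (cat-2 with tph-1). With the replicate block, every count was higher than without it. Against wild type the counts were 4941 (cat-2), 2679 (tbh-1), 5625 (tdc-1) and 2164 (tph-1). The others were 3258 (tdc-1 with tbh-1), 3718 (cat-2 with tph-1) and 2068 (shared). The cause of the rise was not tested. The block also brought tdc-1 in cat-2 from an adjusted p of 0.0638 to 0.0255, tbh-1 in tph-1 from 0.0577 to 0.0275 and tbh-1 in cat-2 against tph-1 from 0.0543 to 0.0235, and it changed no other call on a mutated gene. For the receptors it added lower calls of ser-7 in tdc-1 (adjusted p = 0.0379), ser-3 in tbh-1 (0.042) and ser-3 in cat-2 against tph-1 (0.0277). Over all omissions of a library or replicate number the counts ran from 1550 to 4771 (cat-2), 65 to 2237 (tbh-1), 2313 to 4841 (tdc-1), 655 to 1854 (tph-1), 1076 to 2128 (tdc-1 with tbh-1), 498 to 2460 (cat-2 with tph-1) and 400 to 1914 (shared). The cat-2 transcript in cat-2 mutants ran from a log2 change of -1.03 (without wild type replicate 3) to -0.47 (without replicate 2), and the tdc-1 transcript in tdc-1 mutants from -0.0767 (without replicate 1) to 0.0104 (without replicate 2). Of 37 gene lists 19, 12, 16, 15, 14 and 21 passed (comparisons in the same order), and with an estimated correlation 0, 1, 0, 0, 0 and 0 (the 1 was the amine synthesis list, which holds tbh-1 and had an adjusted p of 0.884 without the mutated genes), with 5, 1, 4, 2, 4 and 8 at unadjusted p under 0.05; fry with directions gave 25, 8, 26, 7, 17 and 18, and fry, mixed gave 37, 31, 35, 29, 31 and 31. Of 786 named calls, 3 were lost with the likelihood ratio test, 13 with DESeq2 size factors, 9 with TMM factors without gonad and collagen lists, 45 with no filter, 2 with the replicate block, 165 without replicate 2, and 607 of 4716 in the omissions of 1 library. Where fewer of them had an adjusted p, 15 of 780 were lost with DESeq2, 125 of 773 with only the 2 groups compared, 23 of 559 with a mean of at least 5 CPM, 231 of 784 without replicate 1 and 211 of 782 without replicate 3. No call turned direction. Counts of 5 or fewer genes against the direction of a list moved by more than 1.5 times in several lists when 1 library was omitted.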

Other observations

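No tests were planned by chromosome, and the shares by chromosome were chosen only after the result was seen. In tdc-1 mutants lower genes were dense on the X chromosome, where 695 of 2234 tested genes fell (31.1%) against 12 to 18.8% on the autosomes. In cat-2 mutants the X chromosome also had the highest share, 20.2% against 11.6 to 17.9%. The X chromosome did not have the highest share of lower genes in tbh-1 (6.67% on X, 8.25% on IV) or tph-1 (7.34% on X, 8.88% on V). Genes that rose were fewest on X in tbh-1, at 14 of 2234 tested genes against 85 of 3142 on V. They were also fewest on X in cat-2 (112) and tdc-1 (68), but not in tph-1 (88 on X, 52 on I). These differences between chromosomes were not tested. Beside the shared rise of B0511.11, its neighbor fbxa-125 on chromosome I rose by 2.1 in tbh-1 mutants. The oocyte gene mex-3 fell in tph-1 mutants (-0.34, SE 0.0467, adjusted p = 0.000143), and F36H5.14 rose there by 3.32 (SE 0.286, adjusted p = 1.27e-06). The gene Y49G5A.1 fell in tdc-1 mutants from 1945 reads to 1 (ratio interval 1.23e-05 to 0.00271) and K03D3.2 from 190 reads to 3 (0.00305 to 0.0443), while F43C11.2 fell in tph-1 mutants from 203 to 3 (0.00273 to 0.0395).

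Wild type replicate 2 lay apart from the other controls on the first principal component (-5.89 against -48 and -54.5), which held 31.1% of the variance. That library also had the lowest sperm list mean of the controls (0.302 against 1.48 and 1.75 mean log2 CPM). Whether the missing Y102A5C.36 transcript of tbh-1 mutants marks a second lesion of that strain can be checked by sequencing chromosome V at 16926922 to 16927445, since these counts cannot separate a deletion from silencing. Amplifying tdc-1 across its annotated exons would check the allele of the tdc-1 strain, whose transcript level did not pass the test. Each genotype was represented by 1 strain. Crossing each allele again into the control strain would separate effects of the allele and its linked region from those of unlinked background differences. It would not separate the allele from differences linked to it. Counting embryos and sperm in the same populations would test whether the lower sperm transcripts of cat-2 and tbh-1 reflect fewer sperm.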
